A study of Fusarium verticillioides with 12 samples.

How the data were processed

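Total RNA from 12 liquid cultures of wild-type *Fusarium verticillioides* strain M3125 was labelled with Cy3 and hybridised to 12 NimbleGen one-colour expression arrays, 1 culture per array. Per the labels' protocols, the fungus was grown in GYAM, a liquid medium used to study fumonisin production, with shaking at 250 rpm and 27 °C, and RNA was purified on columns with a DNase digestion on the column. The labels call the 3 samples of each group biological replicates from separate cultures.

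Samples were grouped from the labels alone. For 6 of the 12 samples the title and the time fields disagree. 3 samples titled 48 h carry 72 h in both the source name and the time field, and 3 titled 72 h carry 48 h there. These were kept as 2 groups, here called the title-48 h group (time field 72 h) and the title-72 h group (time field 48 h). No value was used to decide between the readings. The 24 h and 96 h groups carry 1 time in every label.

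2 kinds of deposited file were used. The series table holds linear intensity values, 1 per feature and array, from 6.60 to 64551. RMA, a method that corrects the background, normalizes probes between arrays and summarises them per feature, is the only tool in the submitters' processing notes, with no version or setting given in the sources used here. The deposited per-sample tables hold, per the file headers, the number of probes of each feature, the mean intensity of its perfect-match probes and the coefficient of variation between them, with no mismatch signal (0 values above 0). On the log2 scale the deposited table correlated with the probe means of the same array at r = 0.954 to 0.989 across features, so the table is linear and runs in the direction of the brightness. The arrays were not on 1 distribution in the table. The log2 medians were 11.53, 11.66 and 11.69 at 24 h, 11.38, 11.43 and 11.53 in the title-48 h group, 11.11, 11.30 and 11.36 in the title-72 h group, and 11.21, 11.21 and 11.19 at 96 h. Which arrays were normalized together is not given in the sources used here. The table was used as the main source because RMA is the method the submitters name and because the per-sample tables hold feature means, not spots. This was decided before any test was run, and the probe means served as an alternative.

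The series' design text speaks of 13288 genes with 13 probe pairs each, and 13201 features were in the table. By the names in the per-sample tables, 12242 were genes known only by a number, 233 were contigs and 287 single reads of expressed sequence tags (ESTs), 434 were introns, and 5 were coding or EST features named for fumonisin (FUM) genes. Of the introns, 48 named 14 FUM genes and 386 did not. 244 introns had 12 probes, 140 had under 8 and 37 had 1. None of the feature names was found in the reference table of 16290 genes (0 matches), so features other than the FUM features are given by their ID on the array, and no coordinates are given.

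The values were taken to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 12 arrays and 4 groups in 1 model (8 residual degrees of freedom, moderated with a prior of 2.85). Tests were a moderated F over the 4 groups, 6 differences between pairs of groups and a linear trend over hours. The trend took the hours of the time fields, and the title hours as an alternative. Calls used a Benjamini-Hochberg adjusted p threshold of 0.05 over all 13201 features. Gene lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one. Of 42 lists fixed before the data were examined, only the fumonisin cluster list had the minimum of 4 members, and 41, among them the lists of conidiation, autophagy and vacuolar proteolysis that stood for other cell states, had 0 members by name. 4 classes of feature (FUM introns, other introns, EST contigs and EST reads) were added as lists after the names had been seen. The naming rule, fixed beforehand, took all fumonisin list members and, since no description is paired with the numbered features, the 2 largest rises and 2 largest falls per comparison against 24 h and between the 2 middle groups. A feature had to be called, to have fully separated groups, and to have its higher group mean in the upper part of all features. The script left the FUM features, which are given on their own, out of the ranking by size, an exception that the rule did not state.

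Alternatives were quantile normalization, scaling to 1 median, the probe means with quantile normalization, leaving out the dimmest 25% of features (3300), a variance trend with robust moderation, an added constant of 16, a fold threshold of 2, a replicate block, the 2 compared groups alone, and leaving out each array in turn. Added after the data had been seen were the omission of both arrays that stood apart from their groups, the probe means with normexp (offset 50) before quantile normalization, a block for the run of array numbers, and a replicate block in the 2 middle groups alone. Between these groups all 3 same-numbered pairs deviated together from their group means (correlations of 0.371, 0.125 and 0.162), which no label explains, and in no other comparison did all 3 exceed 0.1. The run block was fitted to the 8 arrays of the runs that held more than 1 group. Array weights were also tried after the data had been seen. That fit did not converge and was not used. Each array has a number of its own in the per-sample tables, and the numbers fall into 4 runs. Run 1 held 1 array of 24 h, 3 of the title-48 h group and 1 of 96 h, and run 2 held 2 of 24 h and 1 of 96 h. Run 3 held the 3 title-72 h arrays alone and run 4 held 1 array of 96 h. What a run stands for is not given in the sources used here.

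The fitting code was tested on simulated data with 200 changed features among 13201. A simulated log2 change of 2 was recovered for 66% of features in 96 h against 24 h, 58% in the title-48 h group against 24 h, 54% in the title-72 h group against 24 h, 53% between the 2 middle groups, 55% in 96 h against the title-48 h group and 47% in 96 h against the title-72 h group. A log2 change of 1 was recovered for 5% to 16% of features in these 6 comparisons, so a feature that was not called may still have changed. The real comparisons, except 96 h against the title-72 h group, called 2150 to 8003 features. The adjusted threshold is less strict with more changed features, so the simulated rates may understate recovery in those comparisons. The number of arrays, 3 per group, limits the precision. Figures were drawn with matplotlib 3.10.9.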

Results

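Transcript levels of wild-type *Fusarium verticillioides*, a maize pathogen that makes the polyketide mycotoxins called fumonisins, were measured over 4 days in a liquid fumonisin medium. There were 12 arrays in 4 groups of 3 separate cultures. The groups were 24 h, the title-48 h group (titled 48 h, time field 72 h), the title-72 h group (titled 72 h, time field 48 h) and 96 h. Which reading of the middle groups is right stays open, so they are never placed in an order here except in the trend, which is given both ways. Each array gave an RMA intensity for 13201 features.

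2 arrays stood apart from their groups. Title-72 h replicate 1 had a mean correlation of 0.824 with its partners and 96 h replicate 3 one of 0.828, against 0.898 to 0.99 for the 10 other arrays. The median coefficient of variation between the probes of bright features was 70.4% and 62.2% in these arrays and 47.4% to 51.1% in the others. The 5th percentile of the RMA values, a measure of the floor, lay at 5.43 to 6.91 on the log2 scale in the 24 h and title-48 h arrays and at 7.39 to 8.59 in the title-72 h and 96 h arrays.

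**Figure D1:**
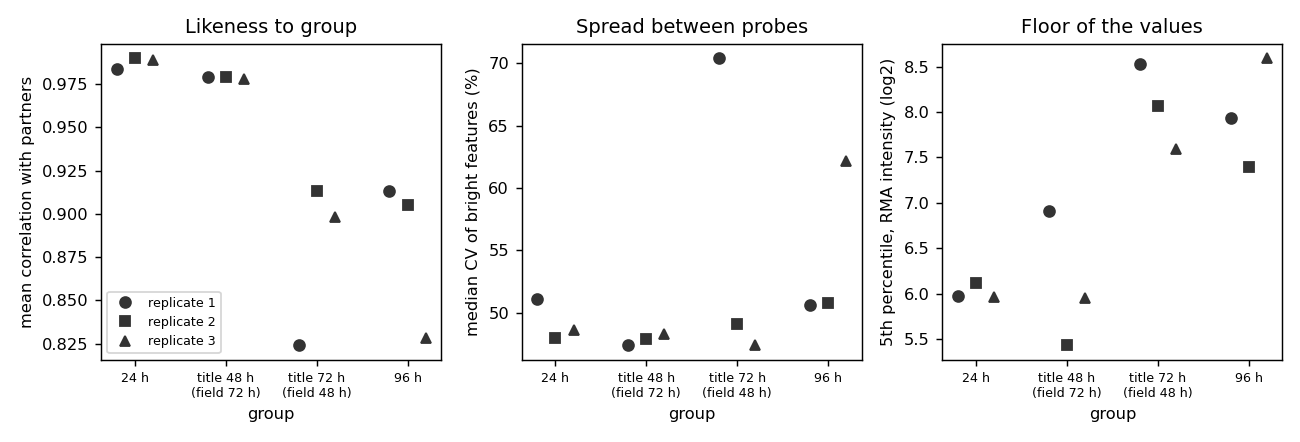
Per-array mean correlation with the group's other arrays, median coefficient of variation between the probes of bright features (%) and 5th percentile of RMA intensity (log2), 1 point per array and 3 replicates in each of the 4 groups. Title-72 h replicate 1 and 96 h replicate 3 lie lowest in the first panel, at 0.824 and 0.828, and highest in the second, at 70.4% and 62.2%.

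The first comparison asked which features differed anywhere among the 4 groups. The 5 fumonisin features were all higher in each later group than at 24 h, as given below. In all, 7975 of 13201 features changed by limma's moderated F test. Quantile normalization lowered this count to 5332, the probe means with quantile normalization to 5779 and median scaling to 7475. Leaving out the dimmest features, which tests fewer features, gave 5444. The variance trend with robust moderation gave 8106 and the added constant 8005. Without the 2 arrays that stood apart, a choice made after seeing the data, the count was 10997.

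In the title-48 h group, fumonisin genes rose over 24 h. FUM10, which encodes an acyl-CoA synthetase, went from 7.29 ± 1.34 to 14.62 ± 1.42 on the log2 scale (SD, n = 3 each), a rise of 7.33 ± 0.71 (SE; limma adjusted p = 3.3e-05). Its 24 h level lay near the floor, and the fold of 160.5 in the RMA values was 44.0 in the probe means. The 24 h replicates read 6.69, 6.37 and 8.83, and without replicate 3 the FUM10 rises were 8.09, 8.96 and 8.98 in the title-48 h, title-72 h and 96 h groups, the last a fold of 505.3. Without title-48 h replicate 3 the title-48 h rises of FUM10 and FUM20 were 8.14 and 4.34. FUM16, another acyl-CoA synthetase, rose by 4.69 ± 0.38 (25.7-fold, adjusted p = 1.0e-05), and FUM20, measured by an EST feature, by 3.49 ± 0.59 (11.3-fold, adjusted p = 0.0011). FUM21, the zinc-cluster transcription factor of the cluster, rose 4.79-fold (log2 2.26 ± 0.47, adjusted p = 0.0036), and FUM15, a cytochrome P450, 3.15-fold (log2 1.66 ± 0.27, adjusted p = 0.00077). All 5 members of the list rose, and all 5 did when adjusted over the list alone. The list's median log2 change was 3.49, against -0.23 for the numbered genes (camera adjusted p = 2.9e-05, and adjusted p = 0.057 with an estimated correlation).

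The 3 title-48 h cultures differed in fumonisin signal. FUM10 read 46482 and 42288 in replicates 1 and 2 and 8120 in replicate 3, and FUM20 read 12786, 9400 and 1907. FUM21 read 10869, 6730 and 12676 in the same order.

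Across all features, 1907 were higher and 2570 lower in the title-48 h group than at 24 h. With arrays scaled to 1 median the split was 2180 higher and 1932 lower. By the naming rule, the largest rises outside the FUM features were those of SEQ0027587, an intron feature with 3 probes (log2 9.46 ± 1.13, adjusted p = 0.00012), and SEQ0025296 (8.62 ± 0.48, adjusted p = 1.9e-06). The largest falls were those of SEQ0025495 (log2 -7.28 ± 0.49, adjusted p = 3.9e-06) and SEQ0026790 (log2 -6.54 ± 0.46, adjusted p = 4.4e-06). SEQ0026790 had a title-48 h mean of 6.20, at the floor of the title-48 h arrays (5th percentiles of 5.43 to 6.91). SEQ0027587 had a 24 h mean of 4.49, under the 5th percentile of each 24 h array (5.96 to 6.12), and its fold of 703.8 was 88.5 in the probe means. The folds of SEQ0025296, SEQ0025495 and SEQ0026790 were 393.0, 155.2 and 93.1 in the RMA values and 81.8, 43.1 and 15.7 in the probe means. The total of 4477 became 7275 with only these 2 groups in the fit and 7795 without the 2 arrays that stood apart.

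The title-72 h group also had more fumonisin transcript than 24 h. FUM10 stood at 15.48 ± 0.23 (SD, n = 3), at the 99.5th percentile of features, a rise of 8.19 ± 0.71 (adjusted p = 1.3e-05), which was 292.1-fold in the RMA values and 80.3-fold in the probe means. FUM16 reached 15.51 ± 0.15, a rise of 5.18 ± 0.38 (36.3-fold, adjusted p = 5.5e-06). FUM20 rose 30.5-fold (adjusted p = 9.0e-05), FUM15 4.34-fold (adjusted p = 0.00012) and FUM21 3.61-fold (log2 1.85 ± 0.47, adjusted p = 0.0073). All 5 members rose, also when adjusted over the list alone. The list's median log2 change was 4.93, against -0.14 for the numbered genes (camera adjusted p = 0.00028, and adjusted p = 0.057 with an estimated correlation). FUM21 read 4062 in replicate 1, which stood apart, and 10438 and 9352 in the others. The title-72 h arrays form a run of array numbers without any 24 h array, so group and run cannot be told apart in this comparison.

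In total, 3650 features were higher and 3475 lower in the title-72 h group than at 24 h. The largest rises by the rule outside the FUM features were those of SEQ0017381 (log2 9.49 ± 0.63, adjusted p = 3.5e-06) and SEQ0017340 (7.999 ± 1.02, adjusted p = 0.00014). With the FUM features ranked too, the FUM14 intron 3afum14 came first (log2 9.61 ± 1.10, adjusted p = 6.6e-05, and 6.63 in the probe means). The largest falls were those of SEQ0022924 (log2 -6.48 ± 0.39, adjusted p = 2.0e-06) and SEQ0025495 (log2 -6.28 ± 0.49, adjusted p = 7.2e-06). Their title-72 h means of 8.21 and 8.34 lay at the floor of the title-72 h arrays (5th percentiles of 7.59 to 8.53). SEQ0017381 had a 24 h mean of 5.91, at the floor, and its fold of 718.3 was 77.9 in the probe means. Without 24 h replicate 3 the rise of SEQ0017340 was 8.69. The folds of SEQ0017340, SEQ0022924 and SEQ0025495 were 255.8, 89.6 and 77.6 in the RMA values and 90.02, 49.6 and 50.4 in the probe means. With median scaling 4455 features were higher and 2201 lower, and without the dimmest 25% of features 1707 were higher and 3327 lower. Quantile normalization called 4632 features, 2206 of them higher.

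At 96 h the fumonisin features remained above 24 h. FUM10 stood at 15.51 ± 0.26 (SD, n = 3), a rise of 8.21 ± 0.71 (adjusted p = 8.6e-06), which was 297.0-fold in the RMA values and 76.7-fold in the probe means. FUM16 rose 36.3-fold (adjusted p = 3.5e-06), FUM20 29.2-fold (adjusted p = 7.3e-05), FUM15 4.07-fold (adjusted p = 0.00012) and FUM21 3.73-fold (adjusted p = 0.0055). All 5 members rose, also when adjusted over the list alone. The list's median log2 change was 4.87, against -0.12 for the numbered genes (camera adjusted p = 0.00041, and adjusted p = 0.057 with an estimated correlation). FUM21 read 3783 in replicate 3, which stood apart, and 10553 and 10993 in the others. Within the 2 runs of array numbers that held both groups, the median log2 difference of the 5 features was 5.33 in run 1 and 4.38 in run 2. In a fit of the 8 arrays of these runs, without 96 h replicate 3 and the title-72 h group, all 5 rose with the run as a block (highest adjusted p = 0.0021).

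In total, 4045 features were higher and 3958 lower at 96 h than at 24 h. The largest rises by the rule outside the FUM features were those of SEQ0017381 (log2 9.48 ± 0.63, adjusted p = 2.1e-06) and SEQ0021093 (8.46 ± 0.46, adjusted p = 7.9e-07). With the FUM features ranked too, 3afum14 came after SEQ0017381 (log2 9.14 ± 1.10, adjusted p = 6.8e-05, and 6.13 in the probe means). The largest falls were those of SEQ0022924 (log2 -6.79 ± 0.39, adjusted p = 9.6e-07) and SEQ0025495 (log2 -6.19 ± 0.49, adjusted p = 4.8e-06). Their 96 h means of 7.90 and 8.42 lay at the floor of the 96 h arrays (5th percentiles of 7.39 to 8.59). The folds of SEQ0017381, which lay at the floor at 24 h, and SEQ0021093 were 712.8 and 352.1 in the RMA values and 73.8 and 79.7 in the probe means, and those of SEQ0022924 and SEQ0025495 were 111.0 and 73.2 against 55.6 and 49.4. With median scaling 4895 features were higher and 2615 lower, and without the dimmest 25% of features 1962 were higher and 3769 lower. The median change of all 13201 features against 24 h was -0.14 at 96 h, -0.23 in the title-48 h group and -0.16 in the title-72 h group, and median scaling moved these to 0.28, -0.05 and 0.21. Over the features left without the dimmest 25%, the medians were -0.55, -0.28 and -0.52. Each fumonisin feature was called as a rise under every scaling tried.

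**Figure D2:**
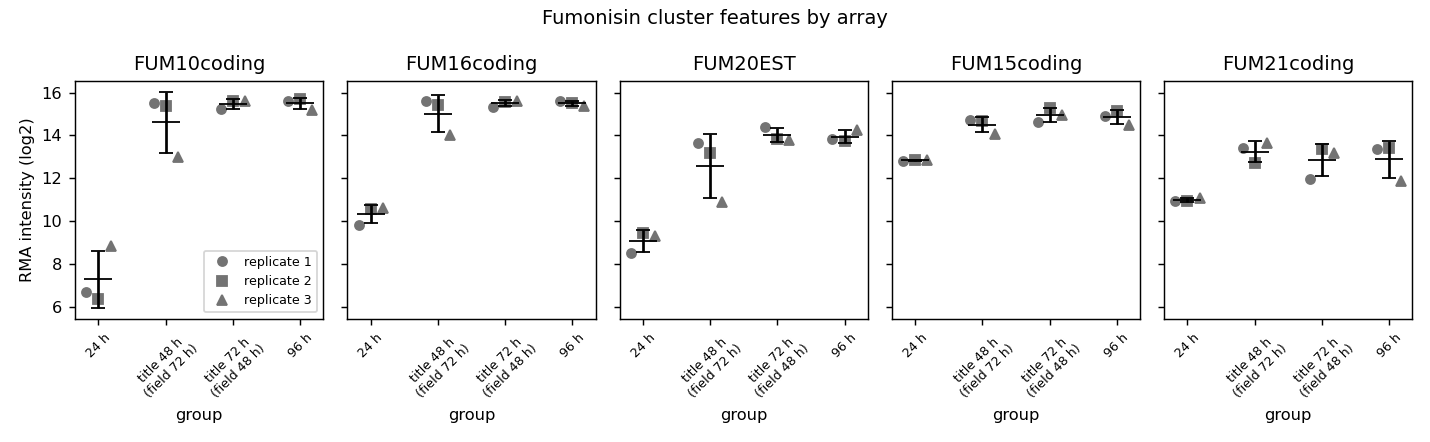
RMA intensity (log2) of the 5 fumonisin cluster features in each of 12 arrays, with the group mean and SD (n = 3). All later arrays lie above the 24 h arrays for each feature, and title-48 h replicate 3 lies below its partners for FUM10, FUM16, FUM20 and FUM15 but not for FUM21.

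Intron features extended the view to introns of 14 FUM genes, 5 of which also had a coding or EST feature. An intron value need not follow the coding or EST value of its gene, as given below. Of 48 FUM introns, 38 rose in the title-48 h group, 42 in the title-72 h group and 43 at 96 h against 24 h, and none of them fell (0 in each comparison). The mean log2 rise at 96 h was 8.84 for the 2 introns of FUM10, 7.81 for the 4 of FUM11, which encodes a tricarboxylate transporter, and 7.30 for the 4 of FUM14, which encodes a condensation-domain protein. The 5 introns of FUM1, the polyketide synthase gene, rose by a mean of 5.59, and the 5 of FUM8, the aminotransferase gene, by 6.99. These introns were dim at 24 h, and 17 of the 48 FUM introns had a 24 h mean below the highest 5th percentile of the 24 h arrays (6.12), so the RMA changes lean on the floor. In the probe means the rises at 96 h were 6.10 for FUM10, 5.64 for FUM11, 4.23 for FUM14, 2.73 for FUM1, with 3 of its 5 introns called, and 4.70 for FUM8. The 3 introns of FUM12 rose by a mean of 5.54 there, above FUM14 and FUM8, and by 6.61 in the RMA values. At 96 h the FUM12 introns 2fum12 and 3fum12 lay at the 100th and 99.8th percentile of features, so their rises may be compressed. The probe means called 26, 34 and 38 FUM introns in the title-48 h, title-72 h and 96 h groups. The smallest RMA means were those of FUM15 (1.12 over 2 introns, 1 of them called) and FUM21 (1.47 over 8 introns, 4 of them called). The FUM15 intron 2afum15 lay at the 94th percentile of features at 24 h and the 99.8th at 96 h, so its rise may be compressed. The median of all FUM introns was 3.80, 4.95 and 5.27 in the title-48 h, title-72 h and 96 h groups (camera adjusted p = 6.2e-18, 4.8e-15 and 2.8e-14, and adjusted p = 0.42 for each with an estimated correlation). The 386 other introns had a median of -0.19 at 96 h (adjusted p = 0.93). Of 287 EST reads, 24 were higher and 61 lower at 96 h than at 24 h, with a median of -0.41 (camera adjusted p = 0.030, and adjusted p = 0.90 with an estimated correlation). Of 233 EST contigs, 44 were higher and 79 lower, with a median of -0.46 (camera adjusted p = 0.31).

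**Figure D3:**
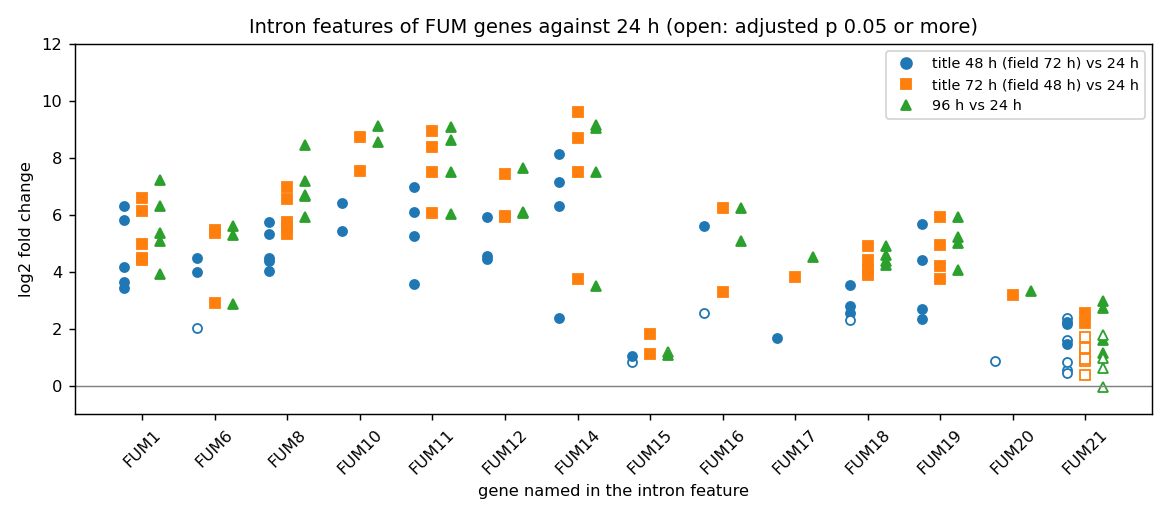
Log2 fold change against 24 h of each intron feature of 14 FUM genes in the title-48 h, title-72 h and 96 h groups, 3 arrays per group, with filled symbols for adjusted p under 0.05. In these RMA values the means at 96 h are highest for FUM10, FUM11 and FUM14 and lowest for FUM15 and FUM21 (1.12 and 1.47), but the FUM14 introns lay at the floor at 24 h, and in the probe means FUM14 (4.23) lies below FUM12 (5.54) and FUM8 (4.70). The FUM15 intron 2afum15 lay at the 94th percentile of features at 24 h already, so its rise may be compressed. The rises of the FUM12 introns 2fum12 and 3fum12, at the 100th and 99.8th percentile at 96 h, may be compressed too.

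Between the middle groups, no fumonisin coding or EST feature was called (0 of 5 by limma, and 0 of 5 with only these 2 groups and a replicate block), with log2 differences, title-72 h minus title-48 h, from -0.41 ± 0.47 for FUM21 to 1.44 ± 0.59 for FUM20 (adjusted p = 0.57 and 0.13). The FUM introns had a median log2 difference of 1.22, with 3 of 48 called, or 6 with only these 2 groups and the block (camera adjusted p = 0.0019, and adjusted p = 0.90 with an estimated correlation). This median rested on title-48 h replicate 3, without which it was 0.29. In fits without the block, 0 of 48 introns were then called by limma (camera unadjusted p = 0.17). None were called without title-48 h replicate 2 or title-72 h replicate 1 or 2 either (0 of 48 each). Leaving out single arrays was not tried in the fit with the block. The largest differences by the rule were those of SEQ0024064 (log2 8.44 ± 0.86, adjusted p = 0.00086) and SEQ0024065 (8.35 ± 0.68, adjusted p = 0.00033), both higher in the title-72 h group. Their title-48 h means of 5.86 and 6.36 lay at the floor (5th percentiles of 5.43 to 6.91), and their folds of 348.4 and 326.9 were 62.4 and 74.04 in the probe means. SEQ0020573 (log2 -4.60 ± 0.54, adjusted p = 0.0024) and SEQ0017003 (log2 -4.02 ± 0.69, adjusted p = 0.015) were lower there, and with only the 2 groups in the fit neither was called without the block (adjusted p = 0.067 and 0.070) and both were with it (adjusted p = 0.00995 for each). Without title-72 h replicate 1 these differences were -5.35 and -4.83. Of 2150 features called, 1869 were higher and 281 lower in the title-72 h group, but quantile normalization called 200 higher and 231 lower, and without the dimmest 25% of features the total was 197. In fits without the block the count also rested on single arrays. It was 74 and 165 without title-48 h replicate 2 or 3, and 191 and 91 without title-72 h replicate 1 or 2. The 3 title-48 h arrays were all in run 1 and the 3 title-72 h arrays all in run 3. Group and run thus cannot be told apart for any difference between the middle groups.

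No fumonisin coding or EST feature was called between 96 h and the title-48 h group (0 of 5 by limma, log2 differences from -0.36 to 1.37). A simulated log2 change of 1 was recovered for 9% of features in this comparison, so differences of this size may have been missed. FUM introns had a median log2 difference of 1.53, with 10 of 48 called as higher at 96 h (camera adjusted p = 0.00070, and adjusted p = 0.90 with an estimated correlation). Without title-48 h replicate 3 the median was 0.63 and 4 were called (camera unadjusted p = 0.016), and 6 were called without title-48 h replicate 2 or 96 h replicate 2. EST reads had a median log2 difference of -0.19 (camera adjusted p = 0.037, and adjusted p = 0.90 with an estimated correlation). In all, 2661 features were higher and 1218 lower at 96 h. Quantile normalization called 828 higher and 891 lower, and median scaling 3120 and 714. The total of 3879 fell to 1085 and 1441 without title-48 h replicate 2 or 3 and to 2247 without 96 h replicate 3. In the 8 arrays of runs 1 and 2, which leave out 96 h replicate 3 and the title-72 h group, 6030 features were called without a block and 4388 with the run as a block, 2202 of them higher and 2186 lower.

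96 h and the title-72 h group were closest, with a correlation of 0.973 between their group means across features. The 24 h means correlated at 0.889 with the title-48 h group, 0.827 with the title-72 h group and 0.782 with 96 h. The title-48 h group correlated at 0.933 with the title-72 h group and 0.894 with 96 h. The title-72 h and 96 h arrays shared no run of array numbers, so a shared run does not explain their closeness. Both groups had a higher floor than the 24 h and title-48 h arrays, which may add to it. The 5th percentiles were 7.39 to 8.59 against 5.43 to 6.91. The runs follow the groups in part and the floor differs with the groups, so these values do not show which labels are right. The 5 fumonisin features differed by log2 -0.09 to 0.05, and 0 of 5 were called. FUM10 and FUM16 lay at the 99.4th to 99.6th percentile of features in both groups, so compressed values could hide a difference in these genes. Only 68 features were called by limma, 50 of them higher at 96 h. The probe means with quantile normalization called 157 higher and 100 lower. The total was 293 without title-72 h replicate 1, but it was 3 and 25 without title-72 h replicate 2 or 3, 4 and 16 without 96 h replicate 1 or 2, 27 and 28 without 24 h replicate 2 or 3, and 37 without title-48 h replicate 1. Without both arrays that stood apart it was 932, with 342 higher and 590 lower. With only the 2 groups in the fit, limma called 0 features, and 582 had an unadjusted p under 0.05. The 386 other introns had a median log2 difference of 0.13 against -0.03 for the numbered genes (camera adjusted p = 0.00016, and adjusted p = 0.62 with an estimated correlation).

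A linear trend over hours was called for 3078 features with the hours of the time fields, 1238 rising and 1840 falling. With the hours of the titles the count was 7598, with 3840 rising and 3758 falling. With median scaling and the time fields, 1500 rose and 1181 fell. The time-field count was 344, 242 and 250 without 24 h replicate 1, 2 or 3, 5062 without title-72 h replicate 1, and 1984 and 1850 without 96 h replicate 1 or 2. A count of calls under either reading does not show which labels are right.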

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

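The omission of both arrays that stood apart, the normexp background, the run block, the replicate block in the middle groups alone and the 4 lists of introns and ESTs were chosen after seeing the data or the feature names. The other alternatives, the comparisons and the fumonisin list were fixed before the data were examined. All 15 tests of the 5 fumonisin features against 24 h were called as rises under every alternative that was fitted to them. The run block could not be fitted to the title-72 h group, which shares no run with 24 h. The list shifts passed 3 of 3 where tested, except with an estimated correlation (0 of 3 by camera, unadjusted p = 0.024 to 0.057, 2 of them under 0.05). Of 730 values of named features under alternatives, 725 kept their direction and call and 5 kept only the direction.

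Quantile normalization gave 4632 features for the title-72 h group against 24 h, 431 for title-72 h against title-48 h and 1719 for 96 h against title-48 h. Probe means with quantile normalization gave 585 for title-72 h against title-48 h, 1951 for 96 h against title-48 h and 257 for 96 h against title-72 h, and with normexp first 654, 2097 and 225. Without the dimmest 25% of features, which tests fewer features, these 3 counts were 197, 1539 and 117. With only the 2 groups in the fit, title-48 h against 24 h gave 7275, title-72 h against title-48 h 28 and 96 h against title-72 h 0. Without both arrays that stood apart, title-48 h against 24 h gave 7795, 96 h against title-48 h 6505, 96 h against title-72 h 932 and the trend 6041. Title hours gave a trend in 7598 features, and in 8520 without these 2 arrays. Between the middle groups, leaving out the dimmest features took the calls from 2150 (1869 higher) to 197 (109 higher). For 96 h against 24 h the split went from 4045 higher and 3958 lower to 1962 and 3769. These counts and directions thus depended on dim features, near a floor that differed between groups. Whether the floor caused these changes was not tested, nor was any other cause beyond the fewer features or arrays.

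Leaving out 1 array at a time gave 6463 to 9091 features for the 4 groups, 6533 to 8923 for 96 h against 24 h, 3316 to 5367 for title-48 h against 24 h, 5510 to 8270 for title-72 h against 24 h, 74 to 2973 for title-72 h against title-48 h, 1085 to 5310 for 96 h against title-48 h, 3 to 293 for 96 h against title-72 h, and 242 to 5062 for the trend.

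Over all groups the replicate numbers did not pair the cultures. Of 18 same-numbered pairs, 6 had deviations correlated above 0.1 (range -0.82 to 0.69), and 2 of 12 arrays correlated best with their own number. The replicate block gave 3 features for 96 h against title-72 h and 1631 for the trend, and moved no other count by over 1.5 times. Only between the middle groups were all 3 same-numbered pairs above 0.1. There the block over all 12 arrays gave 1656 features, and with only these 6 arrays 2343 with the block against 28 without it. That block changed no call of a fumonisin or named feature from the main fit, and called 6 FUM introns in place of 3. The floor, which differed between groups, limits the folds of features that were dim at 24 h and of features that fell to the floor of a later group.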

Other observations

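Tests written only after the result they measure had been seen were those of a raised background, a wrong time label, a failed array, and the 2 arrays that stand apart as a source of the intron difference. The 4 intron tests were first set out for 96 h against the title-48 h group, and the title-72 h comparison was added once the list tests had been seen.

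Introns of FUM genes could be set against the coding or EST feature of the same gene for 15 introns of 5 genes. Over the comparisons between pairs of groups this gave 90 tests, adjusted together, with all arrays and again without the 2 arrays that stood apart. With all arrays, limma called a lower change against 24 h for the intron feature 5afum21 than for FUM21 coding at 96 h (difference of log2 changes -1.94 ± 0.40, adjusted p = 0.018) and for 1fum20 than for the FUM20 EST feature in the title-48 h group (-2.62 ± 0.54, adjusted p = 0.018). Neither intron was itself called as changed there (adjusted p = 0.93 and 0.46). The 1fum20 feature was dim at 24 h and in the title-48 h group (log2 6.91 and 7.78, percentiles 10.3 and 15.7), so the floor may have flattened its change. Without the 2 arrays, 6, 6 and 7 of 15 introns had a lower change against 24 h than the coding or EST feature. The order here is title-48 h, 96 h and title-72 h. In each group these held 1afum21, 3afum21, 5afum21 and 6fum21, all set against the same FUM21 coding values, so they are not independent. The rest came from 1fum20, 2afum15 and 2afum16alt3. At 96 h, 2afum16alt3 was higher relative to FUM16 coding than in the title-48 h group (3.34 ± 0.43, adjusted p = 0.0010) and in the title-72 h group (3.16 ± 0.47, adjusted p = 0.0012). Neither difference was called with all arrays. FUM16 coding lay near the top of the intensity range in these groups, at the 97.3rd to 99.6th percentile, so a difference of intron and coding values there can also reflect a compressed coding value. The intron 2afum15, counted at 96 h and in the title-72 h group, itself lay at the 99.8th and 99.9th percentile there, so its lower change can reflect a compressed intron value. These features were picked after their values were seen.

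Title-48 h replicate 3 had low fumonisin signal. Among features that had risen at least 16-fold in the other 2 cultures, 30 FUM features lay at a median log2 deviation of -3.31 from their partners, and 104 others at -0.01, a difference of -3.30, which argues against a culture closer to 24 h in every induced gene. Of these, 28 FUM features and 11 of the 104 others (10.6%) were over 4-fold below, against 0.885% and 3.31% of others in replicates 1 and 2, so some other induced features were low too. The 8786 other features in the brightness range of these FUM features lay at a median of 0.20 (quartiles 0.02 and 0.36). RMA normalizes between arrays, so this median cannot show a loss of signal over the whole array. In the probe means the median of all features was 4171 in replicate 3, against 4289 and 3296 in replicates 1 and 2. The 95th percentile was 32028, against 30077 and 24275. Its probe spread of 48.3% lay within the 47.4% to 51.1% of the 9 other arrays that did not stand apart. The probe means and this spread argue against a failed array with signal lost throughout. Its mean correlation with its partners, 0.9785, equalled the lowest of those arrays (0.9785 to 0.9901) at this precision, with partners that stood apart left out. A defect of a part of the array was not tested. A culture with lower or later expression of most cluster genes, though not of FUM21, stays open as a hypothesis from 1 culture, for which no biological explanation was tested.

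In the probe means, 9.72% and 14.2% of bright features lay at least 2-fold below their partners in 96 h replicate 3 and title-72 h replicate 1, after centring. The share was at most 1.03% in the 10 others. Centring turns a raised median into lower bright values, so the share cannot exclude a raised background in 96 h replicate 3. Its median was 6006 (partners 3799 and 2692) and its 95th percentile 24725 (28876 and 19751). In title-72 h replicate 1 the 5th percentile was higher, 1112 (745 and 315), and the 95th lower, 19466 (27743 and 26638). Its median was not raised, at 3634 (4760 and 4094). For title-72 h replicate 1 this argues against a raised background alone. The 2 arrays that stood apart had a higher spread between probes of bright features than any other array (the lower of the 2 was 62.2%, against at most 51.1%). Uneven or broken RNA may give this, and RNA integrity was not measured here. They correlated with each other at 0.941, above their 0.824 and 0.828 with their own partners. The only array of run 4 was 96 h replicate 3, so a difference of run cannot be told apart there. Title-72 h replicate 1 shared run 3 with its partners. A wrong time label on title-72 h replicate 1 stays open, since its mean correlation with the other 96 h arrays exceeded that with its own partners by only 0.029. Both values, 0.853 and 0.824, lay under the 0.898 to 0.99 of the 10 other arrays with their partners. This array was thus unlike both groups, under either label.

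Introns of genes other than FUM genes stood higher at 96 h relative to numbered genes, by a median log2 excess of 0.25 over the title-48 h group, which was called only without the 2 arrays that stood apart (camera adjusted p = 0.39 with them, and without them 0.048, or 0.76 with an estimated correlation), and 0.17 over the title-72 h group, called only with the preset correlation. In the same order the excesses were 0.33 and 0.21 with quantile normalization, and 0.145 and 0.141 in the probe means with quantile normalization. Without the 2 arrays that stood apart the excess was 0.19 and 0.27. With all arrays, both intron medians lay at percentile 100 of 10000 lists matched on brightness. The dimmer introns there rose less than the brighter ones, by log2 -0.48 and -0.18. These values argue against those 2 arrays, brightness and an even addition such as genomic DNA as the whole source. The brightness and addition tests were not repeated without the 2 arrays. Introns with 8 or more probes kept 0.15 over the title-72 h group but 0.12 over the title-48 h group, where features with few probes stay open. More unspliced RNA at 96 h may be a candidate explanation, which was not tested, and the title-72 h arrays are confounded with a run of array numbers of their own.

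Whether other splits of the arrays give as many calls was counted for each comparison. For the 4 groups, 1 of 100 splits, the real one, reached 7975, which argues against chance, although the highest other split reached 7929. For the trend, 2 of 100 splits reached 3078 and the highest other gave 7214. 3 arrays against 3 make 10 splits, too few for a share under 0.05. In them the real split was the only 1 to reach its count for 96 h against 24 h (8003, highest other 0), title-48 h against 24 h (4477, highest other 0), title-72 h against 24 h (7125, highest other 0), title-72 h against title-48 h (2150, highest other 0) and 96 h against title-48 h (3879, highest other 2). For 96 h against title-72 h, 2 of 10 splits reached 68. The other gave 853 and had title-72 h replicate 1 and 96 h replicates 1 and 3 on 1 side, both arrays that stood apart among them. With title-72 h replicate 2, title-72 h replicate 3 or 96 h replicate 2 in place of 96 h replicate 1, the counts were 0, 1 and 0. Joining the 2 arrays that stood apart was thus not enough to give many calls, and what the 853 reflect was not tested.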
